A study of Drosophila melanogaster with 2 samples.

How the data were processed

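Whole embryos of a transgenic Drosophila melanogaster line expressing Fer2 with a C-terminal GFP, collected at 6 to 24 h, were the material of both samples, per the labels. Chromatin was sonicated to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The 2 samples are biological replicates by their labels and form 1 group. The replicate numbers 3 and 2 are the submitters' own.

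The authors deposited 4 peak lists on the dm6 build: 1 per replicate, 1 from the pooled alignments, and 1 described as an optimal list thresholded by the irreproducible discovery rate (IDR), derived from the other 3. Per the text files deposited with them, the same control alignment was used for each replicate and for the pool; that control is not analysed here. Because the control is shared, a bias in it reaches both replicates alike, and overlap between their lists cannot reveal it. The peak caller, its settings and the IDR threshold are not given in the sources used here. Each deposited list carries a signal value per peak, a score from the authors' caller whose scale is not stated, and the −log10 of a q-value. The signal value was used only to rank and describe peaks within a list. The deposited −log10 q-values were not used for ranking, since all 2862 thresholded peaks shared the highest value in the list, 3.83, as did 3388 of the 30000 pooled peaks. The p-value column held the mark for no value in every row. The most common width was 370 bp in the pooled list (95.5% of peaks), 380 bp in replicate 2 and 330 bp in replicate 3, so widths mostly reflect a fixed setting. In the thresholded list 1267 peaks were narrower than 370 bp. In the thresholded list 6 rows repeated an interval with another summit, and 2 summits lay outside their interval. They were kept. All 2862 thresholded peaks matched a pooled peak in summit and signal value, and none ranked below 2862 in the pooled list. The lists give no read counts, so depth is unknown and no interval for counting of reads can be given. Intervals and p-values over peaks or genes describe these lists, not the spread between embryo collections.

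Sequence came from the NCBI RefSeq Release 6 assembly, which is dm6, and genes from the Ensembl annotation of the same assembly with transposable elements left out. No peak lay outside the 6 arms 2L, 2R, 3L, 3R, 4 and X or beyond the end of an arm. Coordinates are 1-based. Each summit was given 1 location, in the order promoter (within 500 bp of any TSS), 5' UTR, coding sequence, 3' UTR, non-coding exon, intron, intergenic. The background for locations and arms was the 26695 pooled peaks that no thresholded peak overlapped. The pooled list runs down to a −log10 q-value of 0.152, so this background includes weak calls. Random placements (100, same arm and widths) stand beside these. Words were searched on both strands within 50 bp of the summit and in a flank window of equal length. This flank was centred 250 bp to the right of the same summit. As thresholded peaks had a median width of 370 bp, it lay mostly outside the called peak. Both windows were compared with a two-sided exact McNemar test, adjusted by Benjamini-Hochberg within each family (10 E-box forms, 14 other words, 2080 words of 6 bases). The right flank was fixed as the comparison, with the left as an alternative. A gene was taken to have a peak if a thresholded summit lay in it or within 1 kb. The 22 gene lists were compared with 10000 random lists of protein-coding genes matched on decile of length (two-sided, adjusted over the 22 lists; the smallest p these can give is 0.0002 before adjustment), with Fisher's exact test without matching beside it. The p from these random lists, and that from 10000 random windows around the tagged gene (one-sided, for as many peaks or more), is called a permutation p. Of 675 entries in these lists, 667 were found in the annotation under the symbol given and measured. The lists for families were made from symbol patterns, and some genes are in more than 1 list.

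The genes named were chosen by a rule fixed before the data were examined, as were the tests, lists and alternatives: the tagged gene; the protein-coding gene with the nearest TSS to each of the 20 thresholded peaks with the highest signal value that a peak of each replicate overlaps; and from each list up to 4 members with the highest peak and up to 2 members without a peak, in list order. A gene's rank is that of its highest peak in the thresholded list. For 1 gene chosen by this rule the result is not reported here. The gene cyc in the clock list, and the lncRNA and neighbouring genes of named peaks, are outside that rule and were named after their values were seen. Alternatives left out each replicate by using the 2862 highest peaks of the other replicate's list, used the 1431 highest thresholded peaks, and changed windows, flanks, backgrounds (assembled length entered in kb), gene ranges and matching.

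The tests were first checked on simulated data. With 2862 random sites and nothing implanted, 0 of the 2080 words passed. A word implanted in 286 sites passed with an adjusted p of 8.62e-25. These sites were random and were not given a GC difference between summit and flank. The thresholded peaks had a mean GC content of 32.4% within 50 bp of the summit and 42.8% in the right flank. How the word test behaves under such a difference was therefore not tested by this simulation. Intervals made to overlap at 59.7% were found at 60.1%, the excess coming from chance. Of 200 gene lists drawn at random for the list test, 4% had p under 0.05. For lists of long genes this share was 5% with matching and 99.5% without. All 50 lists of 30 genes in which 60% of members were given a peak passed. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 with fixed seeds. Signal tracks and alignments are not used here.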

Results

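Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the transcription factor Fer2 sits on DNA in whole Drosophila melanogaster embryos aged 6 to 24 h. Fer2 is a basic helix-loop-helix (bHLH) factor, a protein class known to bind the E-box, CANNTG. The flies carried Fer2 fused at its C terminus to green fluorescent protein (GFP), and the antibody was against GFP. The series holds 2 biological replicates, numbered 2 and 3 by the submitters, and no input or other-factor sample, so all results describe 1 group. Each replicate has its own list of 30000 peaks, and a list from the pooled replicates also holds 30000. The same count in each of these lists looks like a set limit rather than a number of sites, but no rule is given. A list kept after the authors' test of irreproducibility between replicates (the thresholded list) holds 2862. The thresholded peaks covered 851.2 kb, were 92 to 740 bp wide with a median of 370 bp, and were the 2862 pooled peaks with the highest signal value. The lists give no read counts, so the depth of each library is unknown here.

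The strongest sites were found in both embryo collections. Each of the 20 highest thresholded peaks ranked 32 or better in the list of each replicate, and the strongest, beside CG14100, was first in both. Of the 2862 highest peaks of replicate 3, 2083 overlapped 1 of the 2862 highest of replicate 2 by at least 1 bp, or 72.8% (95% Wilson interval 71.1 to 74.4), against a mean of 1.34% and at most 1.82% in 100 random placements on the same chromosome arms. In the other direction the share was 74.6%. The thresholded peaks are the highest of the list pooled from both replicates, which favours overlap with each replicate's list. At the 2845 thresholded peaks overlapped by a peak of each replicate, the summits of the replicates lay a median of 35 bp apart (95% interval of the median 34 to 37, quartiles 15 and 63). Across these peaks, which are not independent replicates, the log2 signal values of the replicates had a Pearson correlation of 0.74 and the signal values a Spearman correlation of 0.64. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 peaks farthest from the median in replicate 2, Pearson's r was 0.73. No test across the 2 replicates was run, and the share of shared peaks fell to 46.8% when the whole lists were compared, where random placement gave 14.2%. The whole lists run down to a −log10 q-value of 0.297 in replicate 2 and 0.162 in replicate 3, so they include weak calls.

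The thresholded peaks lay mostly at gene starts. Of the 2862 summits, 1671 (58.4%, 95% Wilson interval 56.6 to 60.2) were within 500 bp of an annotated transcription start site (TSS), against 25.3% of the 26695 pooled peaks that no thresholded peak overlapped (odds ratio 4.14, Fisher's exact test, two-sided, p = 1.96e-272, Benjamini-Hochberg adjusted over 7 locations p = 1.38e-271) and a mean of 13.6% in random placements. Introns away from a TSS held 866 summits (30.3%, against 44.5% of the other pooled peaks), intergenic DNA 267 (9.33%, against 21.4%), and coding sequence 5 (0.175%, against 3.99%). The 1597 summits within 500 bp of the TSS of a protein-coding gene were centred upstream of it, at a median of 118 bp (quartiles 192 and 60 bp upstream), and 85.1% lay on the upstream side. Of the other pooled peaks in this range, 59.9% lay upstream. The 1191 summits beyond 500 bp of any TSS were a median of 2.07 kb from the nearest one (quartiles 1.02 and 4.71 kb).

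**Figure D1:**
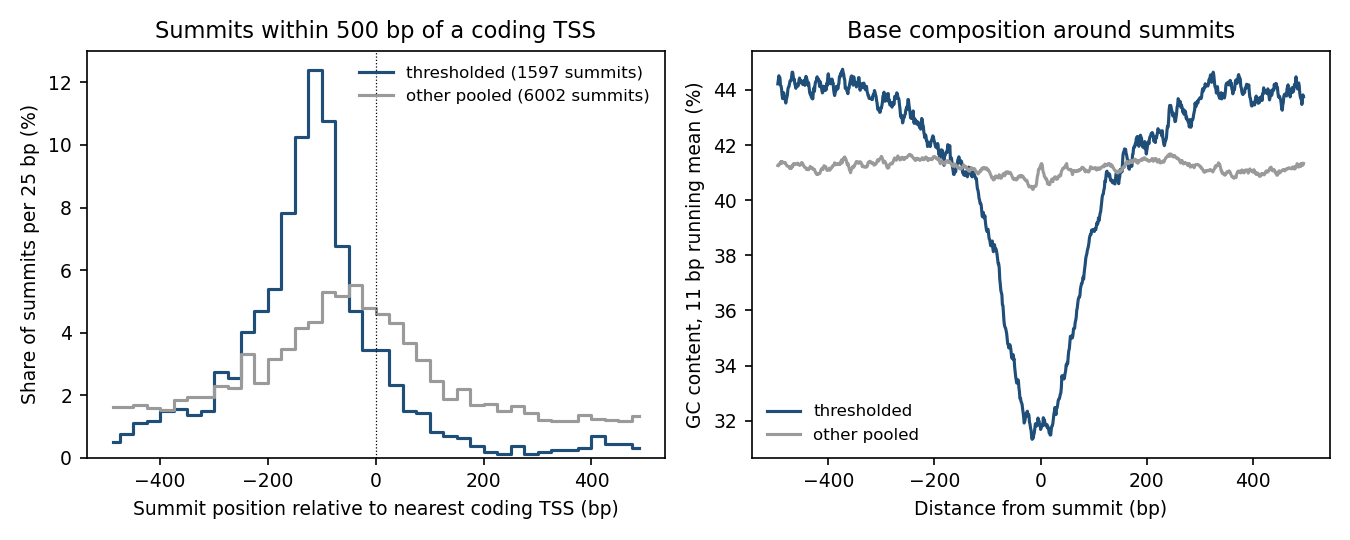
Left, position of summits within 500 bp of the nearest TSS of a protein-coding gene (x axis, bp, negative upstream) as percent of summits per 25 bp (y axis), for 1597 thresholded and 6002 other pooled peaks; right, GC content in percent by distance from the summit in bp. The thresholded summits gather upstream, at a median of 118 bp, and their mean GC content within 50 bp of the summit is 32.4%.

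By the fixed rule, the genes with the nearest TSS to the 20 highest thresholded peaks were CG14100, mRpL41, CG11050, Ugalt, cbt, Art3, ph-p, Pal1, Trl, CG5611, Gapdh2, CG13390, CG18428, CG32772, CG4004, Tcs5, CG1635, CG9663, HmgZ and Lk6. Of these summits 13 were within 500 bp of a TSS and the other 7 in introns. The highest peak (signal value 2295, 3L 19590425 to 19590816, dm6) had its summit 89 bp upstream of CG14100 (FBgn0036889). The next, at 2102 (2R 15217550 to 15217976), was 136 bp upstream of mRpL41 (FBgn0034001), which encodes a protein of the mitochondrial ribosome. The peak ranked 3 (1709, 2L 6612513 to 6612893) was in an intron of CG11050 (FBgn0031836), 1028 bp downstream of its TSS. The peak ranked 4 (1663, X 2703694 to 2704085) was 25 bp upstream of Ugalt (FBgn0024994), a UDP-galactose transporter. The peak ranked 5 (1376, 2L 480908 to 481272) was nearest to cbt (FBgn0043364), a zinc finger factor, but lay in an intron of ush (FBgn0003963), a cofactor of GATA factors. The peak ranked 6 (1306, 3R 15229360 to 15229720) was 126 bp upstream of Art3 (FBgn0038306), an arginine methyltransferase. Others were in or beside ph-p, a Polycomb group gene (1267, X 2137185 to 2137552, 489 bp upstream), Trl, which encodes the GAGA factor (1142, 3L 14759330 to 14759714, intron), and Gapdh2, a glycolytic enzyme (1110, X 15867788 to 15868172, 155 bp upstream). An E-box lay within 50 bp of 3 of the 20 summits, those at CG14100, CG13390 and CG4004. The last was 5083 bp from CG4004 and 467 bp from a TSS of lncRNA:CR44619.

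Ribosomal protein genes and other housekeeping genes carried thresholded peaks more often than genes of like length. Of 13945 protein-coding genes, 3224 (23.1%) had a thresholded summit in the gene or within 1 kb of it. A summit can count for neighbouring genes, and 1282 of the 2862 lay in the range of 2 or more. A peak given for a gene can therefore lie past its 3' end or nearer to another gene. Genes said to have none lacked a thresholded peak, but some had a pooled one. Su(H) and Polr2A had pooled peaks at best ranks of 3003 and 3311, while dpn had no pooled peak. Among 85 ribosomal protein genes, 63 had a peak (74.1%), against a mean of 15.0 in 10000 random lists matched on length (two-sided, adjusted over the 22 lists p = 0.00147; Fisher's exact test without matching, adjusted p = 5.57e-22), and in 57 of the 63 the highest peak was within 500 bp of the gene's own TSS. The highest were at RpS27 (559.2, rank 71, 3R 25247377 to 25247697, summit 9 bp from the TSS), RpL34b (446.5, rank 119) and RpL7 (423.2, rank 131, 2L 10200904 to 10201172, 32 bp). RpS19b and RpL10Aa had none. The excess was smaller, but passed, with random lists matched on pooled peaks near each gene (mean 26.5, adjusted permutation p = 0.0022) or on the number of TSSs, a match added after the data were seen (mean 28.4, adjusted p = 0.00147). Among 11 housekeeping genes, 9 had a peak against a mean of 2.97 (adjusted permutation p = 0.0033), led by Gapdh2 (rank 11), the chaperone gene Hsp83 (312.1, rank 253, 3L 3192985 to 3193238), the translation elongation factor gene eEF2 (rank 1004) and the actin gene Act5C (rank 1157). Gapdh1 and Polr2A had none. The housekeeping excess did not pass with the replicate 2 list alone (7 of 11 against a mean of 2.93, adjusted permutation p = 0.105). It did not pass with the 1431 highest peaks (5 of 11 against 1.78, adjusted permutation p = 0.231) or gene bodies only (4 of 11 against 1.02, adjusted p = 0.197). Nor did it pass with random lists matched on pooled peaks (9 against 4.20, adjusted permutation p = 0.0513).

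Gene families used mainly by sense organs and by the cuticle carried fewer peaks than matched genes. Of 179 chemoreceptor genes, 8 had a peak (4.47%), against a mean of 37.6 in random lists (adjusted permutation p = 0.00147). They included Ir68b (293.4, rank 300, 3L 12125074 to 12125306), Or85f (rank 846), Gr89a (rank 897) and Or88a (rank 987), and Or85c and Gr93c had none. Only 1 of the 8 had its highest peak within 500 bp of its own TSS. The summits given for Ir68b, Or85f and Gr89a lay past the 3' ends of these genes. Of 92 cuticle protein genes, 2 had a peak against a mean of 14.4 (adjusted permutation p = 0.00147), Cpr76Ba (306.8, rank 268, 3L 19516619 to 19516849) and Cpr73D (rank 1954). Ccp84Ab and Ccp84Af had none. Of the 2 cuticle genes with a peak, 0 had it within 500 bp of the gene's own TSS. The cuticle deficit did not pass with gene bodies only (1 of 92 against a mean of 3.02, adjusted permutation p = 1.0). It did not pass either when peaks were given to the gene with the nearest TSS (3 of 92 against 9.62, adjusted permutation p = 0.109). With random lists matched on the number of pooled peaks near each gene, the chemoreceptor deficit did not pass (8 against a mean of 13.1, adjusted permutation p = 0.51). Some chemoreceptor genes lie side by side or share the same coordinates, while the random lists drew genes independently. The permutation p-values of families with such neighbours can therefore be too small.

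**Figure D2:**
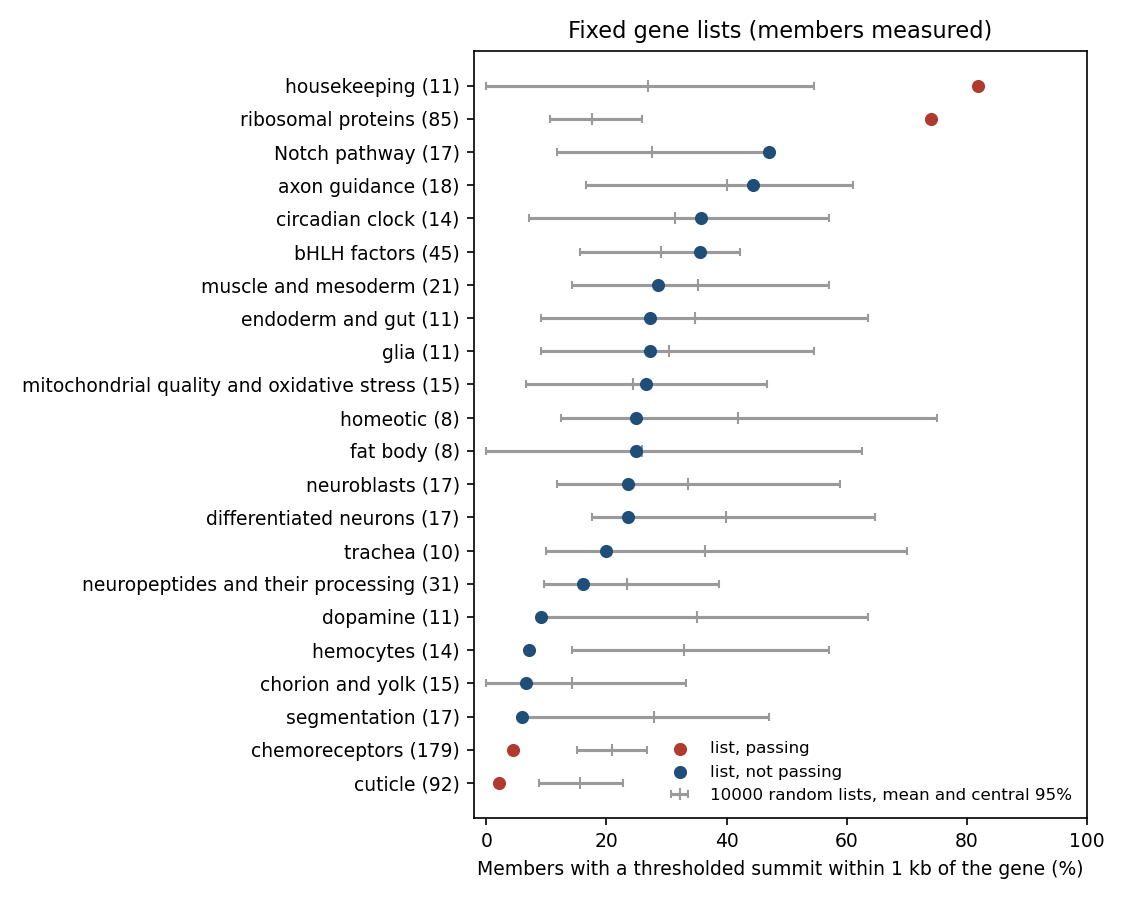
Percent of the measured members of each fixed gene list with a thresholded summit in the gene or within 1 kb (x axis), 1 row per list (y axis, number of members in brackets), with the mean and central 95% of 10000 random lists matched on length in grey. Red points passed at an adjusted p under 0.05: 74.1% of ribosomal protein genes and 81.8% of housekeeping genes lie above the random lists, 4.47% of chemoreceptor and 2.17% of cuticle genes below.

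None of the lists of developmental, neural or clock genes passed in either direction. Fer2 is known for its part in dopamine neurons and the circadian clock of adult flies. Of 14 clock genes 5 had a peak against a mean of 4.40 (adjusted permutation p = 1.0): sgg, a kinase (264.3, rank 363, X 2646307 to 2646556), Pdp1 (rank 687), dco (rank 1304), cwo (rank 1479) and cyc, while per and Pdf had none. Only 1 of the 5 had its highest peak within 500 bp of its own TSS, and the cyc summit lay past that gene's 3' end. Of 11 dopamine genes, 1 had a peak against a mean of 3.86 (adjusted permutation p = 0.338), the receptor gene DopEcR (rank 2095), and ple and Ddc, the synthesis enzymes, had none. Of 15 genes of mitochondrial quality and oxidative stress, 4 had a peak against 3.66 (adjusted permutation p = 1.0), namely Marf (rank 394), Sod2 (rank 763), Keap1 (rank 877) and cnc (rank 1594), and park and Pink1 had none. Of 45 bHLH genes, 16 had a peak against 13.1 (adjusted permutation p = 0.863), led by gce (479.4, rank 104, X 15298316 to 15298655), trh (rank 315), sim (rank 520) and net (rank 737), and dpn and emc had none. Of 17 Notch pathway genes, 8 had a peak against 4.69 (adjusted permutation p = 0.338), led by mam (373.3, rank 177), numb (rank 308), neur (rank 720) and E(spl)m3-HLH (rank 880), and Ser and Su(H) had none.

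The lists of tissue markers did not pass after adjustment either. Of 17 genes of differentiated neurons, 4 had a peak against a mean of 6.78 (adjusted permutation p = 0.615): elav, which encodes a neuronal RNA-binding protein (596.8, rank 61, X 523314 to 523660), ChAT (rank 550), Syx1A (rank 2289) and Sh (rank 2845), and nSyb and Syt1 had none. Of 31 neuropeptide genes, 5 had a peak against 7.24 (adjusted permutation p = 0.863), led by amon, a prohormone convertase (624.4, rank 51), ETH (rank 258), svr (rank 755) and Proc (rank 2339), and Pdf and Dh31 had none. Axon guidance genes had 8 of 18 against 7.21 (adjusted permutation p = 1.0), with PlexA (rank 379), Fas3 (rank 1289), NetB (rank 1482) and sli (rank 1586) the highest and robo1 and robo2 without a peak. Glial genes had 3 of 11 against 3.34 (adjusted permutation p = 1.0), moody (rank 116), Gs2 (rank 762) and pnt (rank 816), without repo and gcm. Neuroblast genes had 4 of 17 against 5.72 (adjusted permutation p = 0.868), brat (rank 261), pros (rank 1582), grh (rank 1618) and hb (rank 1968), without dpn and ase. Muscle and mesoderm genes had 6 of 21 against 7.40 (adjusted permutation p = 0.953), led by sls (rank 433), kirre (rank 606), tin (rank 745) and Mef2 (rank 976), without Mhc and Act57B. Gut genes had 3 of 11 against 3.83 (adjusted permutation p = 1.0), fkh (rank 599), bowl (rank 1232) and cad (rank 1945), without lab and srp. Tracheal genes had 2 of 10 against 3.64 (adjusted permutation p = 0.863), trh and bnl (rank 2106), without btl and vvl. Of 14 hemocyte genes only ush (rank 5) had a peak, against 4.61 (permutation p = 0.0496 before and 0.206 after adjustment), and Hml and srp had none. Of 8 fat body genes, Lsp2 (rank 1152) and Adh (rank 1403) had peaks against 2.07 (adjusted permutation p = 1.0), and Lsp1beta and Lsp1alpha had none. Of 8 homeotic genes, Antp (rank 1402) and Abd-B (rank 1767) had peaks against 3.36 (adjusted permutation p = 0.868), and lab and pb had none. Of 17 segmentation genes, 1, hb, had a peak against 4.76 (adjusted permutation p = 0.206), and en and inv had none. Of 15 chorion and yolk genes, 1, Yp3 (rank 1252), had a peak against 2.14 (adjusted permutation p = 0.953), and Yp1 and Yp2 had none. The segmentation deficit passed with genes extended by 5 kb (2 of 17, adjusted permutation p = 0.0475) and with the replicate 2 list alone (0 of 17, adjusted p = 0.0396). The summits given for ETH, sli, Lsp2 and Yp3 lay past the 3' ends of these genes. Of the 8 axon guidance genes with a peak, 1 had its highest peak within 500 bp of its own TSS.

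E-boxes were less frequent at the summits than beside them. Of the 2862 thresholded peaks, 32.4% (95% Wilson interval 30.7 to 34.2) had CANNTG within 50 bp of the summit, against 39.7% in a window of equal length centred 250 bp to the right (ratio 0.82, exact McNemar test, two-sided, p = 1.16e-08). The left flank had 40.6%. The other pooled peaks had 40.8% at the summit. Pooled peaks matched on GC content and on promoter class (within 500 bp of a TSS or not) had a mean of 33.4% (central 95% of 100 sets 31.7 to 34.8). That range held the 32.5% of the 2859 thresholded peaks that could be matched. Position within the promoter class was not matched. Of the 10 forms of the E-box, 7 were less frequent at the summit at an adjusted p under 0.05 over the 10 forms, among them CACGTG (0.804% against 1.82%, adjusted exact p = 0.00229) and CAGCTG (3.07% against 5.17%, adjusted p = 0.000568). Within 25 bp of the summit 4 forms were less frequent, and CACGTG did not pass there (adjusted exact p = 0.0683) or against the other pooled peaks (adjusted p = 0.0607). CATATG was more frequent (4.30% against 2.48%, adjusted exact p = 0.000568), but not against the left flank (adjusted p = 0.0951) or within 25 bp (adjusted p = 0.144). Against the matched pooled peaks, only CAAATG among the forms lay outside the central 95% of its sets, below it (8.53% against a mean of 10.2%). CACGTG (0.804% against a mean of 0.707%) and CAGCTG (3.08% against 2.76%) lay inside. The summits were also AT-rich: GC content within 50 bp was 32.4% ± 9.30 (SD over 2862 peaks), against 42.8% ± 10.03 in the right flank and 40.8% ± 9.94 at the summits of the other pooled peaks.

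Among 14 other words fixed in advance, 5 were more frequent at the summit and 2 less. The homeodomain core (TAATTA) was in 11.5% of peaks at the summit and 4.93% in the flank (adjusted exact p = 5.02e-18), the MEF2 site in 8.63% and 3.74% (adjusted p = 5.39e-14), the GATA site in 23.1% and 15.4% (adjusted p = 1.98e-13), the DRE (TATCGATA), a core promoter element, in 1.64% and 0.804% (adjusted p = 0.00981), and the BEAF site (CGATA) in 15.5% and 12.8% (adjusted p = 0.0083). The DRE, at a ratio of 2.04, did not pass with the replicate 2 list alone (ratio 1.41, adjusted exact p = 0.219). With the 1431 highest peaks it did not pass either (ratio 1.92, adjusted exact p = 0.16). The BEAF site, at a ratio of 1.21, did not pass in these 2 settings (ratio 1.11 and 0.98, adjusted exact p = 0.192 and 0.868). The GAGA repeat was in 0.769% and 3.63% (ratio 0.21, adjusted exact p = 2.07e-14), with a ratio of 0.58 against the other pooled peaks (adjusted exact p = 0.0183). ACGTCA, a word fixed as a control although it holds the core of CREB-type sites, was in 1.68% and 3.18% (adjusted exact p = 0.000604). It did not pass against the other pooled peaks (adjusted exact p = 0.137). It lay inside the sets matched on GC content (1.68% against a mean of 1.53%). Of the 640 words of 6 bases with 3 G or C bases, as in ACGTCA, 267 passed as less frequent and 13 as more frequent. Words for Su(H), Zelda, core promoter motifs 1 and 6, AP-1, Grainy head and tramtrack did not pass. Su(H) and tramtrack were less frequent at the summit against the other pooled peaks (adjusted exact p = 0.00815 and 0.000359) and with the replicate 3 list alone (adjusted p = 0.000409 and 0.00665). Against pooled peaks matched on GC content and on promoter class, 21 of the 24 words (the E-box forms and these 14) lay inside the central 95% of 100 matched sets. Of all 2080 words of 6 bases, counted on both strands, 393 were more frequent at the summit and 907 less. All 36 words made of A and T alone passed as more frequent, and 35 of the 36 words made of G and C alone as less frequent. The word with the smallest exact p was AAATAT, in 38.2% of peaks at the summit and 16.7% in the flank (adjusted exact p = 3.11e-71).

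**Figure D3:**
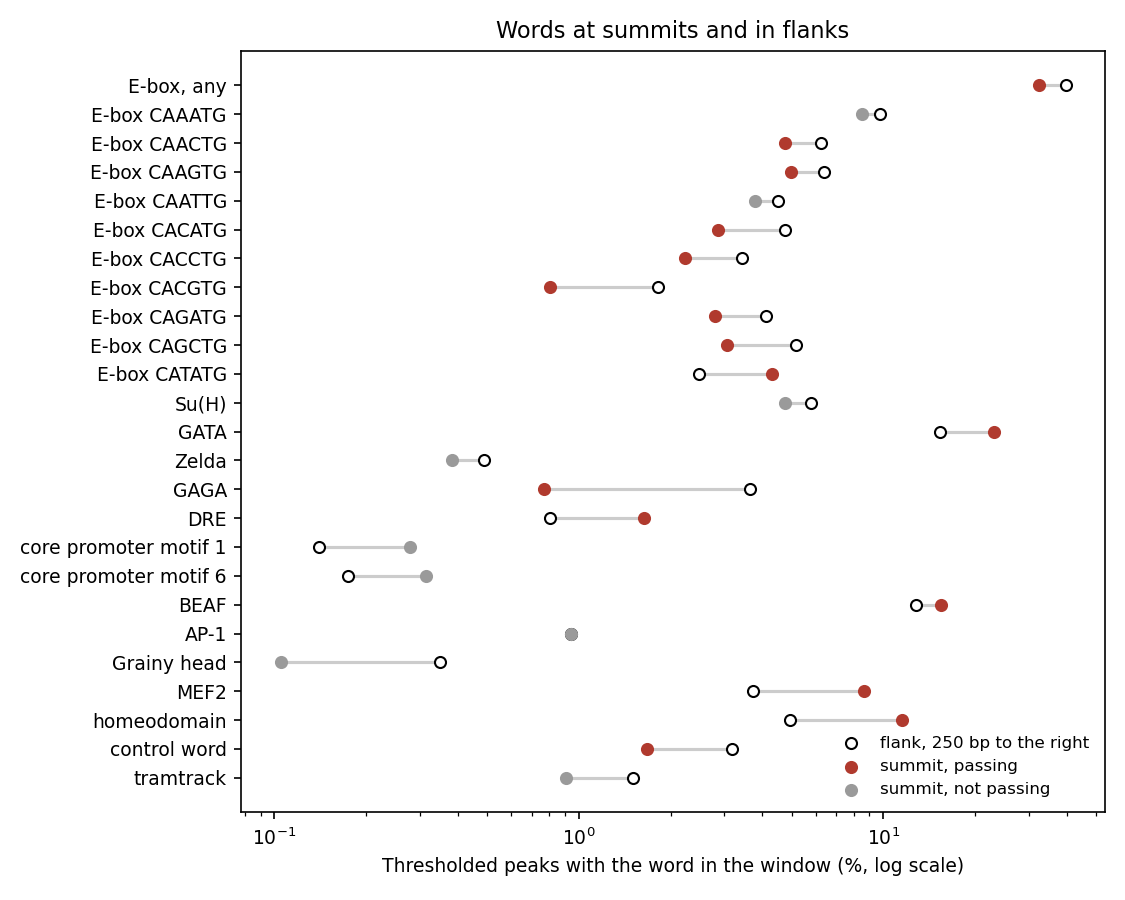
Percent of the 2862 thresholded peaks with each word (x axis, log scale; 1 row per word) in the window within 50 bp of the summit (filled points) and in a window of equal length centred 250 bp to the right (open points). Red points passed at an adjusted p under 0.05 (unadjusted for any E-box); any E-box falls from 39.7% in the flank to 32.4% at the summit, and GATA, MEF2 and homeodomain words lie higher at the summit.

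E-boxes were less frequent in peaks at gene starts than in distal peaks. They were within 50 bp of the summit in 29.9% of the 1671 peaks near a TSS and 36.0% of the 1191 distal peaks (ratio 0.83, Fisher's exact test, two-sided, p = 0.000573). By signal value, 30.8% of the top quartile of 715 peaks and 35.4% of the bottom quartile had an E-box (ratio 0.87, exact p = 0.072), which did not pass. It passed within 25 bp of the summit (ratio 0.79, exact p = 0.0478) and with the replicate 2 list alone (ratio 0.74, p = 0.000172).

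Peaks were spread over all 6 chromosome arms. Thresholded peaks per Mb ran from 20.6 on 3L to 23.0 on 2L among the long arms, and chromosome 4 had 7.42. Against the other pooled peaks, 3 arms differed after adjustment over the 6 arms (Fisher's exact test, two-sided). Chromosome 4, which is short and largely heterochromatic, held 10 peaks or 0.349%, against 0.903% (odds ratio 0.38, adjusted exact p = 0.00658). Arm 3L held 20.2% against 22.7% (odds ratio 0.86, adjusted exact p = 0.00658), and X 17.3% against 15.5% (odds ratio 1.13, adjusted p = 0.0347). Against assembled length, or with the replicate 2 list alone, only chromosome 4 passed. With the 1431 highest peaks none of the 6 arms did: chromosome 4 had the same odds ratio of 0.38 (adjusted exact p = 0.131).

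Peaks also lay beside the tagged gene. Fer2 (FBgn0038402) is on the minus strand of 3R, from 16149369 to 16151312 (dm6), and 3 thresholded peaks were within 5 kb of it, with no others within 50 kb. The highest (196.5, rank 654, 3R 16153444 to 16153585) was in intergenic DNA with its summit 2235 bp upstream of the Fer2 TSS. Another (107.2, rank 1744, 3R 16151606 to 16151975) was 479 bp upstream of that TSS. The remaining peak (118.2, rank 1522, 3R 16146737 to 16147106) was 2447 bp beyond the 3' end of Fer2, where the genes Mic26-27 and CG5916 start. None of these summits had an E-box within 50 bp. Over 20 kb either side of the gene this was 0.715 peaks per 10 kb, and 12.04% of 10000 random windows held as many (permutation p = 0.12, one-sided), so no excess was called. With 10 kb either side it was 1.37 per 10 kb, and 3.98% of windows held as many (permutation p = 0.0399). A tagged transgene can add copies of its own locus to the genome. Whether this line carries such copies, and how far they reach, is not given in the sources used here, and these values do not separate them from binding. The pooled list had 11 summits within 20 kb, against a mean of 9.44 in random windows, and each replicate's own list had 14, against 9.46.

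**Figure D4:**
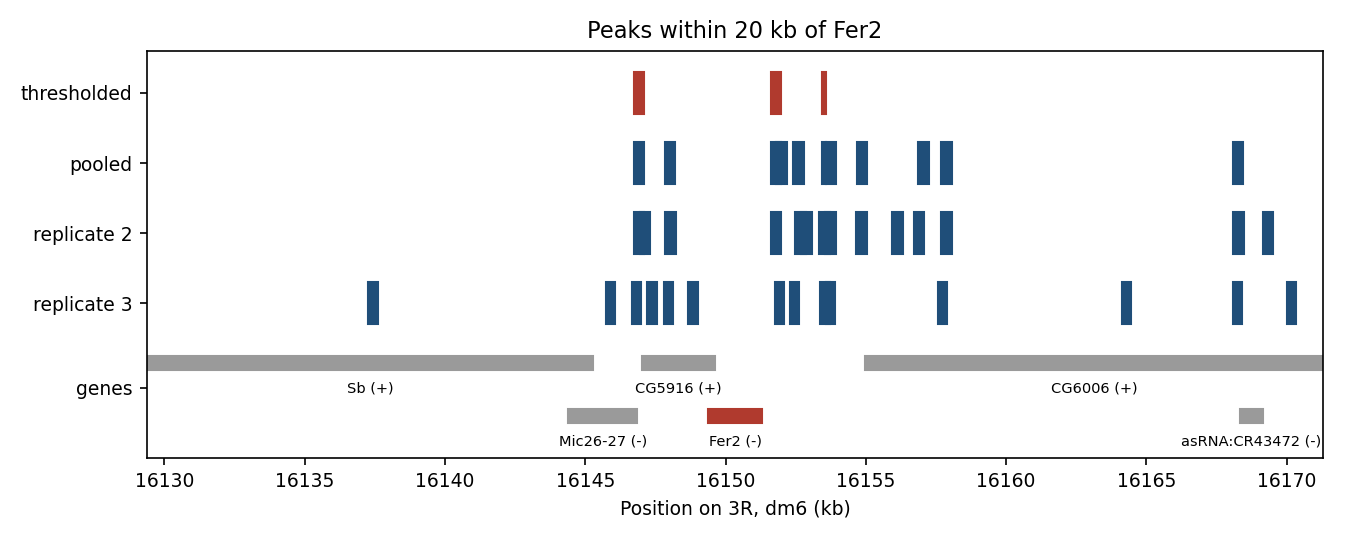
Map of 3R in dm6 (x axis, kb) from 20 kb before to 20 kb after Fer2, with 1 row for each peak list and boxes for peaks drawn to scale; genes are below, with their strand, and Fer2 is in red. The 3 thresholded peaks are all within 5 kb of Fer2.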

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

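The promoter share (47.1% to 68.4%), the lower E-box share at summits (ratio 0.71 to 0.87), its lower share at promoters than in distal peaks (ratio 0.76 to 0.92) and both counts of 6-base words stayed on the same side of their thresholds, or within 1.5 times, under every alternative run for them. Of 94 alternative values of main results, 68 did so; of 366 for single words, arms and lists, 288 did, 29 lost and 8 gained their call, 39 with no call changed direction (AP-1 from a ratio of 1) and 2 with a call did. The share of replicate 3 peaks found in replicate 2 depended on the rule: 58.3% with 50% reciprocal overlap, 66.6% with summits within 100 bp, 74.6% with the top 1431 peaks, 65.0% with the top 5724, 46.8% with whole lists, and 74.6% the other way round. The median summit distance was 29 bp in the 1431 highest peaks. Within 25 bp of the summit, 0 E-box forms were higher and 4 lower, and the E-box ratio between signal quartiles was 0.79; with the left flank 0 forms were higher. With the 1431 highest peaks, 3 other words were higher, 0 arms differed and 1 list was higher. Arms differing fell to 1 against assembled length, where X had an odds ratio of 0.98. Lists higher and lower were 1 and 1 with gene bodies only, 1 and 1 when matched on pooled peaks; 1 list was lower by nearest TSS. Around Fer2, peaks per 10 kb were 1.37 within 10 kb. The BEAF word turned to a ratio of 0.98 in the 1431 highest peaks. Leaving out each replicate gave 3 to 5 other words higher, 2 to 4 lower, a signal quartile ratio of 0.74 to 0.87, 1 to 3 arms and 1 to 2 lists higher. The cause was not tested for any of these. Matching on TSS number was added after seeing the data; 2 lists were higher and 2 lower. The highest pooled peaks equal the thresholded list, and no peak lies off the 6 arms, so replacing the list by the highest pooled peaks or keeping these arms alone changed nothing, and neither is counted. No paired analysis was possible because there is 1 group. Depth is unknown.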

Other observations

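The gene lists of the first paragraph, the bound on the share of peaks with an E-box, the matching of single words on GC content, the E-box share at ribosomal and housekeeping genes and the matching of gene lists on TSS number were chosen after the results were seen. Genes of the mitochondrial ribosome carried peaks more often than genes of like length: 33 of 73 had one, against a mean of 10.02 in 10000 random lists (two-sided, adjusted over 5 added lists permutation p = 0.0010). This list was chosen after mRpL41 and the peak shared by Art3 and mRpS10 had been seen among the strongest. Without mRpL41 and mRpS10, 31 of 71 had a peak, against means of 9.82 matched on length, 16.1 on pooled peaks and 15.7 on TSS number (adjusted permutation p = 0.0010, 0.0010 and 0.0005). The highest were at mRpL41 (rank 2), mRpS10 (rank 6, in the shared start region with Art3), mRpS23 (898.5, rank 24, 2L 13835297 to 13835627) and mRpL23 (692.0, rank 38). Proteasome subunit genes did not pass (11 of 40 against 7.26, adjusted permutation p = 0.209), with Rpn5 the highest (rank 62, its summit past the 3' end of the gene). Odorant-binding protein genes (2 of 51 against 6.81, adjusted permutation p = 0.119), seminal fluid protein genes (1 of 47 against 4.51, adjusted p = 0.168) and Jonah protease genes (0 of 16 against 2.11, adjusted p = 0.209) did not pass either, though all 3 were lower by Fisher's exact test without matching on length (adjusted p = 0.000567, 0.000228 and 0.0399). Matched on TSS number, the odorant-binding (mean 10.8, adjusted permutation p = 0.0020) and seminal fluid lists (mean 10.1, adjusted p = 0.0010) passed as lower, and matched on pooled peaks they did not (adjusted p = 0.678 and 0.653).

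A thresholded summit lay in or within 200 bp of 2365 of 13945 protein-coding genes (17.0%), 151 of 3261 genes of non-coding RNA (4.63%), 5 of 290 tRNA genes (1.72%, 95% Wilson interval 0.739 to 3.97), 4 of 269 snoRNA genes (1.49%), 2 of 32 snRNA genes (6.25%, interval 1.73 to 20.1) and 0 of 99 rRNA genes (upper bound 3.74%). These shares were not tested against each other or matched on gene length. The intervals treat genes as independent, and how well reads can be placed in repeated genes was not examined.

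E-boxes were less frequent at thresholded summits than beside them, for a protein of a class known to bind them. Low GC content of the summits is a candidate explanation: in 100 sets of pooled peaks matched to 2859 of the thresholded peaks on GC content and on distance to a TSS (within 500 bp or not), a mean of 33.4% had an E-box (central 95% of sets 31.7 to 34.8), and the thresholded peaks, at 32.5%, lay inside that range. Matched in this way, 21 of the 24 single words lay inside the range of their sets, GATA (23.1% against 22.9%) and the homeodomain core (11.5% against 11.2%) among them; the BEAF site (15.5% against 13.7%) and the MEF2 site (8.60% against 7.70%) were above it and CAAATG (8.53% against 10.2%) below. The tables argue against the hypothesis that most thresholded peaks mark binding at an E-box within 50 bp of the summit, since 32.4% had one, with an upper bound of 34.2%. That share was known when the hypothesis was written, so it is a count over the list, not a test of a prediction. The summits of the replicates lay within 50 bp of each other at 64.8% of 2845 peaks, which limits how well this window holds a site. Binding at a minority of peaks, at E-boxes farther off, or through other proteins stays open, as does the source of the AT-rich summits, and the series holds no second group in which a biological explanation could be tested.

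Ribosomal protein and housekeeping genes carried peaks more often than genes of like length. The number of TSSs near each gene is argued against as the whole cause. With random lists matched on this number, 63 of 85 stood against a mean of 28.4 (adjusted permutation p = 0.00147) and 9 of 11 against 4.09 (adjusted p = 0.0275). Closely spaced promoters were tested only through this number, and the distance between promoters was not matched. Matched on the number of pooled peaks, the ribosomal list still passed (mean 26.5, adjusted permutation p = 0.0022) and the housekeeping list did not (mean 4.20, adjusted p = 0.0513). The highest peaks of these genes, 70 in all, had an E-box at the summit in 31.4% of cases and in the flank in 32.9% (exact McNemar p = 1.0), and their GC content at the summit was 44.2% ± 9.28 (SD), against 32.4% ± 9.30 over all thresholded peaks. Binding of the tagged protein and open promoter DNA recovered whatever protein is tagged cannot be told apart here, because no input, untagged or other-factor sample is analysed here.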
